A study of Rattus norvegicus with 19 samples.

How the data were processed

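The samples are 19 microarrays of biotin-labelled cRNA from 6 ug of total RNA each, from microdissected deep motor cortex of rats, in 6 groups: control (n = 4) and days 1, 3, 7, 14 and 49 after a dorsal column lesion (n = 3 each), taken from the labels. The probe annotation is that of the Affymetrix rat whole-genome array. The values are log2 signals, 1 per probe set and array, deposited by the authors after RMA (background correction, quantile normalization and a robust summary of the probes), per the submitters' processing notes; its version is not given in the sources used here. RMA forces the arrays to a common distribution, so a shift of all transcripts would not be seen. Scan dates and processing batches were not analysed here, so a batch that follows a group cannot be told apart from it. For arrays, their number limits the precision.

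The table holds 31099 probe sets with no missing value. The 57 array controls were kept out of the tests and used for array quality, which left 31042. Symbols came from the platform annotation, updated through the gene ID for 20764 probe sets and through an accession for 2, against a gene table of a newer assembly from which no coordinates were used; 66 kept the annotation's symbol. In all, 20826 probe sets had 1 symbol, 436 several and 9780 none here; none was named from a probe set with several. Each of 14217 genes was represented by its probe set with the highest mean over all arrays. Signals of different genes are not compared, since probe sets differ in response.

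Each probe set was tested with limma 3.58.1 in R 4.3.3, in 1 fit of 6 group means over all 19 arrays with eBayes defaults, two-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. Comparisons were each of 5 times against control, each time against the one before it, and a moderated F test of the 5 differences. The fit had 13 residual and 2.76 prior degrees of freedom. Gene lists, 31 of them with 872 members of which 754 were matched, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over lists and times; camera with an estimated correlation and fry stood beside it. Members were also adjusted over the list alone. "Higher" and "lower" for list members without a p give the sign of the difference.

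Genes were named by a rule fixed before the data were examined. For each time it took up to 10 genes that rose and 10 that fell with the largest change among those past the threshold whose lesion arrays lay beyond all control arrays. Where fewer than 3 passed, it added the genes of smallest p up to 5. It took the 10 smallest p of the F test, up to 4 members of each called list past the threshold or the 2 of smallest p, and Atf3, Jun, Gap43, Sprr1a, Gfap, Bcl11b, Crym and Fos whatever they showed. Cell type and tissue lists were given by their median. Genes outside the rule are said to be named after their values were seen; Ccl7, Gfap, Atf3 and other list members that the rule names are not among them.

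Alternatives planned before the data were examined were: centring each array on its median, quantile normalization again, a filter at the median probe set, eBayes with trend and robust settings, array weights, 1 probe set per gene, the replicate number as a block, the myelin list mean as a covariate, a minimum absolute log2 change of 0.5, a fit of only the 2 groups, and each replicate left out in turn; for lists also an estimated correlation and all probe sets of each gene. Replicate numbers are shared by the groups in the labels, which do not say that they mark a common day or litter. Deviations from the group means correlated by 0.166, 0.117 and 0.269 in the 3 pairs of control and day 1 arrays of like number, so the blocked count is given beside the day 1 count. Chosen after seeing the data were fits without day14 replicate 2 and day49 replicate 2, alone and with the beta-actin 3' minus 5' difference as a covariate.

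The test was tested on simulated data for day 1 against control over 31042 probe sets, with 200 changed. It recovered 17 of 50 changed by 0.5 on the log2 scale, 42 of 50 changed by 1, and 50 of 50 changed by 2 or by 3, with 8 false calls. Without the 2 arrays that stand apart it recovered 42, 49, 50 and 50, with 3 false calls. The simulated noise was independent between probe sets and had the same spread on every array. In the data probe sets are not independent and the 2 arrays lie farther from the others. The recovery and false calls therefore describe the simulated setting and may differ in the data. Correlations between times were compared with 20 simulated sets of unchanged groups against shared controls. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.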

Results

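RNA of the deep motor cortex was measured on 19 arrays from adult female rats after the dorsal columns of the spinal cord were cut at the third cervical segment. The cut severs the corticospinal axons, which arise from layer V pyramidal neurons, so the neurons lie in the dissected cortex and the injury lies far away in the cord. The tissue was the lower part of the forelimb and hindlimb motor cortex, which holds layer V together with glia, vessels, interneurons and other layers. There were 4 control arrays and 3 arrays each at days 1, 3, 7, 14 and 49 after the lesion. The labels do not say whether control rats had a sham operation. They name separate samples, and p-values of single probe sets measure the spread between these samples. List p-values of camera at its preset correlation take list members as nearly independent, so they rest mainly on the spread over genes. Standard errors over members do so too. The number of arrays limits the precision.

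Most arrays were closely alike, and 2 stood apart. In 17 arrays the median correlation with the others lay between 0.994 and 0.997, against 0.931 for day14 replicate 2 and 0.969 for day49 replicate 2. The signal of the 3' end of beta-actin minus that of its 5' end, a measure that grows when RNA is broken, was 2.24 on the log2 scale in day14 replicate 2. It lay between 0.877 and 1.29 in the 17 arrays. The same difference for GAPDH was 3.18 in day14 replicate 2 and at most 0.196 in the 17 arrays. The mean of the spiked-in control transcripts was 10.2 in both of these arrays and at most 9.72 in the 17. Among the 17, day49 replicate 3 had the highest beta-actin difference. All 19 arrays were used as planned, and values without these 2 arrays, a choice made after seeing the data, stand beside the main ones.

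**Figure D1:**
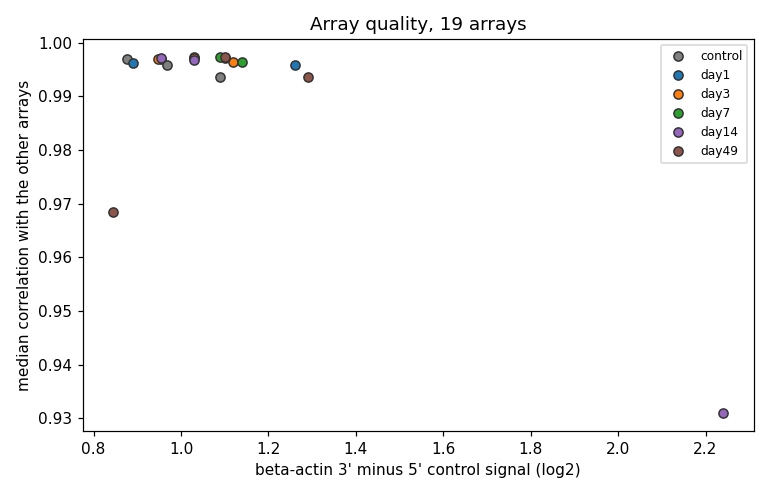
Each point is 1 of the 19 arrays; the horizontal axis is the beta-actin 3' minus 5' control signal (log2), the vertical axis the array's median correlation with the other arrays, and colours mark the groups. Day14 replicate 2 lies at 2.24 and 0.931 and day49 replicate 2 at 0.845 and 0.969, apart from the other 17 arrays.

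The first comparison asked which transcripts of motor cortex differ from control 1 day after the lesion. A small set of genes rose at day 1. Agt, which encodes angiotensinogen and is made by astrocytes in brain, rose from 4.84 ± 0.05 (SD, n = 4) to 5.88 ± 0.16 (SD, n = 3) on the log2 scale, a 2.05-fold rise with adjusted p = 0.00688. Ifitm3, an interferon-inducible membrane protein, rose by 0.89 (SE 0.14, adjusted p = 0.0242). Igfbp6, a binding protein of insulin-like growth factors, rose by 0.86 (SE 0.12, adjusted p = 0.0148), and Lbp, the lipopolysaccharide-binding acute phase protein, by 0.82 (SE 0.11, adjusted p = 0.0148). Pla1a, a phospholipase, rose by 0.82, the matrix protein gene Spon2 by 0.81, the retinoic acid binding protein gene Crabp2 by 0.78 and Lgi4 by 0.64, with adjusted p between 0.00768 and 0.0242. Rem2, a small GTPase that limits calcium channels, fell by 0.46 (SE 0.07, adjusted p = 0.0346). In each of these 9 genes the 3 lesion arrays lay beyond all 4 control arrays, which the naming rule requires and which is therefore no result about them. Of all probe sets 6.94% did so in 1 direction or the other, against 5.71% by chance.

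In all, limma called 11 of 31042 probe sets at day 1, 9 higher and 2 lower, against 510 at an unadjusted p under 0.05. The second lower one is a probe set of the collagen gene Col15a1, not the brightest of that gene, which fell by 0.88 (adjusted p = 0.0346) and was named after its value was seen. Lower with small p, but not past the threshold, were Myoc (-0.56, adjusted p = 0.058), Art3 (-0.31, 0.141), Lum (-0.93, 0.192) and Cd48 (-0.35, 0.561). Of these, Lum encodes the collagen-binding lumican. The count fell to 6 without control replicate 1 or control replicate 2, to 2 without control replicate 4, to 5 without day1 replicate 1 and to 0 without day1 replicate 2. Without the 2 arrays that stand apart it was 68, with 46 higher and 22 lower, and all 11 were among them. With the replicate number as a block it was 3, those of Agt, Spon2 and Crabp2. The 510 at an unadjusted p under 0.05 are fewer than the share of 0.05 of all probe sets that no change would give. The same holds below for day 3 (282), day 7 (275) and the F test (1368). It holds too for day 3 against day 1 (574) and day 7 against day 3 (174). The 2 arrays that stand apart enter the shared spread of the fit. Without them the unadjusted counts at days 1, 3 and 7 were 2210, 1415 and 1517.

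Those 68 included further genes, of which Steap4, Chi3l1, Inmt, Prodh, Fxyd1, Timp4, S1pr3, Aldh1a1 and Pmp2 were named after their values were seen. Steap4 was higher by 0.93 (adjusted p = 0.000817), the copper-binding acute phase gene Cp by 0.78 (0.0232), the metallothionein gene Mt2A by 0.71 (0.000817) and the inflammatory transcription factor gene Cebpd by 0.55 (0.00426). Chi3l1 (1.12), Inmt (1.01), Prodh (0.76), Fxyd1 (0.66), Timp4 (0.62) and S1pr3 (0.50) were higher too, with adjusted p between 0.00122 and 0.0382. Lum (-0.93), Aldh1a1 (-0.77), Pmp2 (-0.63) and Myoc (-0.56) were lower, with adjusted p between 0.0102 and 0.0489. In the fit of 19 arrays these genes had adjusted p between 0.058 and 1.

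**Figure D2:**
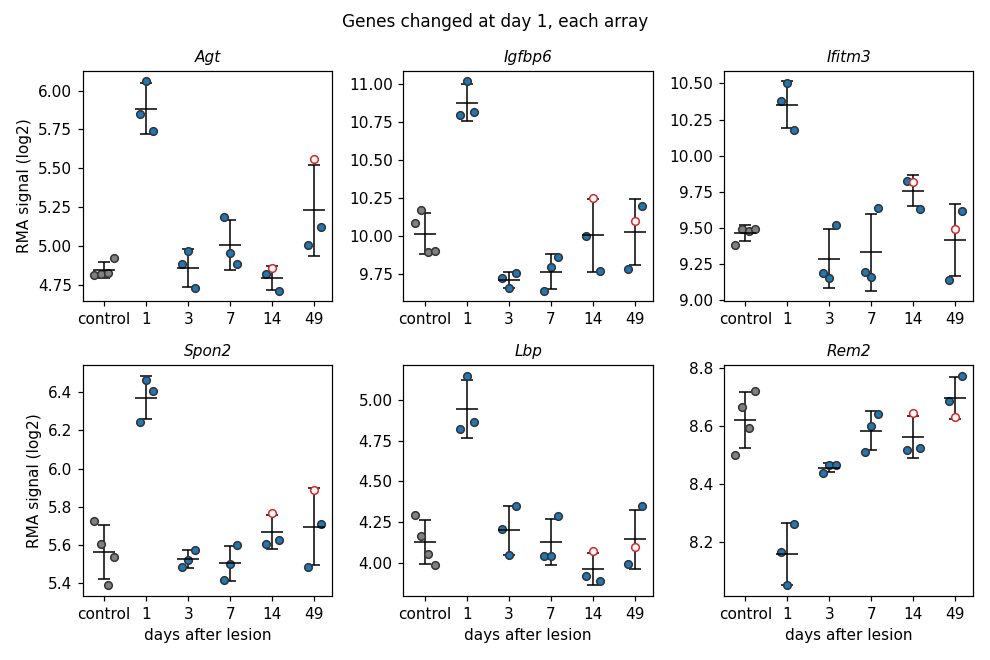
Each panel gives the RMA signal (log2) of 1 gene on each array by days after the lesion; bars are the group mean ± SD (n = 4 for control, 3 otherwise), grey points are control arrays, and open red points are day14 replicate 2 and day49 replicate 2. Agt lies between 4.81 and 4.92 in control and has a mean of 5.88 at day 1 and 4.86 at day 3.

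Of 31 gene lists fixed before the data were examined, 13 were called at day 1 with camera at its preset correlation, 9 higher and 4 lower. None was called at any time with an estimated correlation. Fry called none for a shift in 1 direction and 1, the regeneration associated genes at day 14 (adjusted p = 0.0471), for change in either direction. Of 20 reactive astrocyte genes 15 were higher, with a median of 0.10 (adjusted p = 1.86e-05; adjusted p = 0.078 with an estimated correlation). Gfap, the astrocyte intermediate filament, went from 5.18 ± 0.22 to 5.82 ± 0.08, and Gfap (0.64) and Cp (0.78) passed when adjusted over the list alone (both 0.00773). Of 35 cytokine and acute phase genes 29 were higher, with a median of 0.08 (adjusted p = 0.000558; adjusted p = 0.402 with an estimated correlation), and the endotoxin co-receptor Cd14 (0.76) and Cebpd (0.55) passed when adjusted over the list alone (both 0.0156). Of 26 glucocorticoid response genes 21 were higher (median 0.04, adjusted p = 0.00599; adjusted p = 0.372 with an estimated correlation), and Mt2A (0.71) and Cebpd passed when adjusted over the list alone (both 0.0116).

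Genes of interferon response and antigen presentation went the other way at day 1. Of 32 such genes 28 were lower, with a median of -0.18 (adjusted p = 1.87e-09; adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone, 4 were lower, namely the class II antigen presentation genes Cd74 (-0.86), RT1-Da (-0.87) and RT1-Bb (-0.92) and the chemokine gene Cxcl9 (-0.38), and 1, Ifitm3, was higher; the 4 lower genes were named after their values were seen. Microglia and macrophage markers had a median of 0.12 (17 of 27 higher, adjusted p = 0.0149; adjusted p = 0.575 with an estimated correlation). Among them Gpnmb (0.89) passed when adjusted over the list alone (0.0044), and the complement gene C1qc was 0.62 above control with adjusted p = 1.

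Regeneration associated genes, which rise in neurons that regrow an axon, were called higher at day 1 (27 of 36 above 0, median 0.07, adjusted p = 0.00381; adjusted p = 0.345 with an estimated correlation). Atf3, a transcription factor induced in axotomized neurons, went from 5.92 ± 0.12 to 7.65 ± 0.85, a difference of 1.73 that passed when adjusted over the list alone (0.0135) and not over all probe sets (0.415). Gadd45a was 0.43 above control (adjusted p = 1). Immediate early genes were also called higher (21 of 27, median 0.08, adjusted p = 0.0096; adjusted p = 0.114 with an estimated correlation), with Vgf at 0.39 and Egr1 at 0.48 (both adjusted p = 1). Endothelial and pericyte markers had a median of 0.08 (18 of 24 higher, adjusted p = 0.00111; adjusted p = 0.161 with an estimated correlation), with the drug transporter gene Abcg2 at 0.43 (0.0336 over the list alone) and Anpep at 0.24. Perineuronal net and matrix genes had a median of 0.06 (adjusted p = 0.00599; adjusted p = 0.114 with an estimated correlation), with the aggrecan-cleaving protease gene Adamts4 at 0.60 (0.00366 over the list alone) and Col4a2 at 0.31. Of 42 ribosomal protein genes 40 were higher by a small amount (median 0.04, adjusted p = 0.00937; adjusted p = 0.402 with an estimated correlation), with Rpl26 at 0.09 and Rps9 at 0.08.

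The other lists called lower at day 1 were cholesterol biosynthesis, axon growth genes and voltage gated ion channels. Of 19 cholesterol genes 16 were lower (median -0.11, adjusted p = 0.00823; adjusted p = 0.402 with an estimated correlation), with Insig1 at -0.15 and Lss at -0.18. Axon growth genes had a median of -0.04 (adjusted p = 0.0298; adjusted p = 0.254 with an estimated correlation), with Marcks at -0.30 and Dcx at -0.20. Ion channel genes had a median of -0.04 (adjusted p = 0.0377; adjusted p = 0.402 with an estimated correlation), with Cacnb4 at -0.35 and Kcnab1 at -0.19. The axon growth call was lost without the 2 arrays that stand apart (adjusted p = 0.0698; 0.307 with the beta-actin covariate), although these are not in the comparison and the list mean stayed at -0.05 (-0.04 with the covariate). The ion channel call was lost with that covariate (0.11; mean -0.06, against -0.07 with all arrays), both calls with a filter at the median probe set (0.0707 and 0.0925), and the cholesterol call with the replicate block (0.0993). The interferon, cytokine, reactive astrocyte and endothelial calls of day 1 held with each array of the compared groups left out in turn. The regeneration call was lost without control replicate 3, the immediate early call without control replicate 3 or day1 replicate 2, the glucocorticoid call without day1 replicate 2 and the microglia call without control replicate 3 or day1 replicate 3. The matrix and cholesterol calls were lost without control replicate 4 or day1 replicate 3, the ribosomal call without control replicate 1 or day1 replicate 3, the axon growth call without control replicate 1, day1 replicate 2 or day1 replicate 3, and the ion channel call without control replicate 1, control replicate 3 or day1 replicate 3. Without day1 replicate 3 the count of lists was 7. Outside the called lists, Aspa of the myelin list, named after its value was seen (-0.47; 0.0209 over the list alone), and Lum of the meningeal list (-0.93; 0.00245) were lower at day 1.

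The second comparison asked what differed from control at day 3, and the third how day 3 differed from day 1. By day 3 the 9 genes described at day 1 were near control, with differences between -0.30 and 0.07. Between day 1 and day 3 7 of these fell: Igfbp6 (-1.17, SE 0.13, adjusted p = 0.00358), Ifitm3 (-1.07, 0.0139), Agt (-1.02, 0.00681), Pla1a (-0.93, 0.0199), Spon2 (-0.85, 0.00681), Crabp2 (-0.73, 0.0199) and Lgi4 (-0.69, 0.021). These 7 genes make up all 8 called probe sets, since Igfbp6 has 2. In all, 574 probe sets had an unadjusted p under 0.05. Day 1 against control and day 3 against day 1 use the same 3 day 1 arrays, by which these genes were named. The fall is therefore no independent check of the rise. Agt was at 4.86 ± 0.12 and Igfbp6 at 9.71 ± 0.05 (SD, n = 3) at day 3, against 4.84 and 10.02 in control. The count fell to 4, 0, 1, 2 and 4 without day1 replicate 1, day1 replicate 2, day3 replicate 1, day3 replicate 2 and day3 replicate 3. It was 63 without the 2 arrays that stand apart.

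Against control, limma called 0 probe sets at day 3, with 282 at an unadjusted p under 0.05, and 0 without the 2 arrays that stand apart. The genes with the smallest p, none past the threshold (adjusted p = 1 for each), were Arhgap32 (0.45), Adamts4 (0.43), Gpnmb (0.56), Arih1 (0.23) and Sema6a (0.42) above control and Ccn3 (-0.91), Aspn (-0.60), Wfdc1 (-0.70), Plpp2 (-0.26) and Gsn (-0.34) below it. For Arih1 the gene's 3 other probe sets had the opposite sign, and for Sema6a 1 of its 5 did.

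At day 3, 10 lists were called, 3 higher and 7 lower. Interferon and antigen presentation genes were lower again (28 of 32, median -0.16, adjusted p = 4.57e-12; adjusted p = 0.078 with an estimated correlation), with the antiviral genes Rsad2 at -0.67 and Oas1a at -0.47. Meningeal and choroid plexus genes, which mark tissue at the brain surface and ventricle, had a median of -0.13 (18 of 22 lower, adjusted p = 4.8e-05; adjusted p = 0.345 with an estimated correlation), with the matrix genes Mgp at -0.63 and Ogn at -0.54. Unfolded protein and stress response genes had a median of -0.08 (21 of 24 lower, adjusted p = 0.00381; adjusted p = 0.078 with an estimated correlation), with the transcription factor genes Atf4 at -0.26 and Ddit3 at -0.15. Cholesterol genes had a median of -0.09 (adjusted p = 0.00381; adjusted p = 0.345 with an estimated correlation), with Idi1 at -0.14 and Insig1 at -0.11. Glucocorticoid response genes had a median of -0.08 (adjusted p = 0.00547; adjusted p = 0.356 with an estimated correlation), with Sult1a1 at -0.48 and Nfkbia at -0.22. Clock genes had a median of -0.08 (adjusted p = 0.0211; adjusted p = 0.114 with an estimated correlation), with Hlf at -0.38 and Dbp at -0.43. Endothelial markers had a median of -0.07 (adjusted p = 0.0223; adjusted p = 0.345 with an estimated correlation), with Emcn at -0.25 and Kcnj8 at -0.18.

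Higher at day 3 were regeneration associated genes (median 0.04, adjusted p = 0.00381; adjusted p = 0.345 with an estimated correlation), with Atf3 at 0.98 and Sema6a at 0.42. Perineuronal net and matrix genes had a median of 0.07 (adjusted p = 0.00556; adjusted p = 0.113 with an estimated correlation), with Adamts4 at 0.43 and Adamts5 at 0.30. Axon growth genes had a median of 0.06 (32 of 42 higher, adjusted p = 0.0333; adjusted p = 0.26 with an estimated correlation), although the members with the smallest p were lower, Ntn1 at -0.61 and Wnt5a at -0.16. None of these list members passed over all probe sets or over its list alone. The clock call was lost without the 2 arrays that stand apart (adjusted p = 0.0728; 0.0565 with the beta-actin covariate), although these are not in the comparison and the list mean stayed at -0.11 (-0.14 with the covariate). With the myelin list mean as a covariate the clock (0.0599), cholesterol (0.0642), stress response (0.108), axon growth (0.156), meningeal (0.193) and endothelial (0.626) calls were lost, and with all probe sets of each gene the matrix call (0.101). The interferon, meningeal and stress response calls of day 3 held with each array left out in turn. The regeneration call was lost without control replicate 3, the cholesterol call without control replicate 4, the glucocorticoid call without day3 replicate 3, the matrix call without control replicate 4 or day3 replicate 1, the endothelial call without control replicate 1, control replicate 2 or day3 replicate 3, and the clock call without control replicate 3, control replicate 4 or day3 replicate 3. The axon growth call was lost without control replicate 2, 3 or 4 or day3 replicate 2 or 3.

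The fourth comparison asked what differed 7 days after the lesion, where Vip, Gal, Atf3 and Npy had the largest differences among the named genes. Gal, which encodes the peptide galanin, went from 6.67 ± 0.14 in control to 7.93 ± 0.82 (SD, n = 3), a difference of 1.26 (SE 0.26) that passed when adjusted over the regeneration list alone (0.00741) and not over all probe sets (adjusted p = 1). Vip, vasoactive intestinal peptide, was 1.76 above control and Npy, neuropeptide Y, 1.22 above it, with large spread at day 7 (SD 1.67 and 1.28). Atf3 was 1.22 above control (SD 0.98). Other genes of smallest p were Il24 (0.25), Snhg11 (0.38) and Rem1 (0.23) above control and Cysltr2 (-0.55), Acp5 (-0.37), Cpne3 (-0.66), Ccn3 (-0.64) and Gsn (-0.31) below it. All had adjusted p = 1. Limma called 0 probe sets, with 275 at an unadjusted p under 0.05, and 0 against day 3, with 174.

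At day 7, 7 lists were called. Regeneration associated genes were higher (26 of 36, median 0.08, adjusted p = 1.87e-09; adjusted p = 0.078 with an estimated correlation). Interneuron markers were called higher (median 0.07, adjusted p = 0.00566; adjusted p = 0.078 with an estimated correlation) with Vip and Npy leading, both also members of the regeneration list; this call was lost without day7 replicate 2, and its adjusted p was 0.0971 without the 2 arrays that stand apart, with the list mean at 0.21 in both fits. Interferon and antigen presentation genes remained lower (27 of 32, median -0.19, adjusted p = 3.5e-13; adjusted p = 0.078 with an estimated correlation), with the ubiquitin-like gene Isg15 at -0.86 and Rsad2 at -0.61. Meningeal genes had a median of -0.10 (adjusted p = 4.87e-05; adjusted p = 0.345 with an estimated correlation), with the proteoglycan gene Dcn at -0.37 and Slc13a4 at -0.41. Perineuronal net and matrix genes had a median of 0.09 (adjusted p = 0.00381; adjusted p = 0.104 with an estimated correlation), with Adamts4 at 0.30 and Sparc at 0.13. Cell cycle genes had a median of 0.07 (21 of 24 higher, adjusted p = 0.00415; adjusted p = 0.406 with an estimated correlation), with Cdk1 at 0.29 and Ccnb2 at 0.23. Ribosomal protein genes had a median of 0.03 (adjusted p = 0.00599; adjusted p = 0.382 with an estimated correlation), with Rps13 at 0.15 and Rpl26 at 0.08. With the myelin covariate the cell cycle (adjusted p = 0.0599) and meningeal (0.0632) calls were lost, with the beta-actin covariate and without the 2 arrays the ribosomal call (0.309; mean 0.01, against 0.04 with all arrays), and with all probe sets of each gene the matrix (0.122) and interneuron (0.359) calls. The regeneration, interferon and meningeal calls held with each array left out in turn. The matrix call was lost without control replicate 3 or 4, the cell cycle call without day7 replicate 3 and the ribosomal call without control replicate 1 or day7 replicate 1.

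The fifth comparison asked what differed at day 14, where the means of the neuropeptide genes Vip, Gal and Npy were above those of day 7. Vip went from 3.90 ± 0.13 in control to 6.70 ± 0.39 (SD, n = 3), a difference of 2.81 (SE 0.51). Gal went from 6.67 ± 0.14 to 8.43 ± 0.31, a difference of 1.76 (SE 0.26), and Npy from 6.34 ± 0.26 to 8.04 ± 0.43, a difference of 1.69. Atf3 stood at 7.54 ± 0.32, 1.62 above control, and Csrp3, a muscle LIM protein gene, at 6.18 ± 0.91, 1.47 above control. Ecel1, a peptidase gene induced by nerve injury, was 0.59 above control. All 3 day 14 arrays lay above all 4 control arrays in each of these 6 genes, which passed when adjusted over the regeneration list alone (from 0.000206 for Gal to 0.042 for Ecel1). None passed over all probe sets, with adjusted p = 0.178 for Gal, 0.301 for Vip and 0.365 for the other 4. Npy, Csrp3 and Ecel1 were named after their values were seen.

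Without day14 replicate 2 and day49 replicate 2 the day 14 differences were 2.88 for Vip, 1.62 for Gal, 1.80 for Npy, 1.44 for Atf3 and 1.98 for Csrp3, with adjusted p between 0.203 and 0.701. Sprr1a, another gene of axon injury, was 0.54 above control (adjusted p = 0.365), and Gap43, the growth cone protein gene, 0.13 above it (0.388). Gfap was at 5.88 ± 0.25, 0.70 above control, and passed when adjusted over the reactive astrocyte list alone (0.00633). Casp4 (0.49), Ltbp2 (0.49) and Il24 (0.40) were among the smallest p above control (adjusted p of 0.293 to 0.301). Slc7a5 (-1.19), Myo5a, Cers4 (-0.55), Alox5ap (-0.45) and Apba3 (-0.44) were below it (0.301 to 0.365). With the 2 arrays that stand apart left out, Slc7a5 was at -0.85, Myo5a at -0.57, Cers4 at -0.39 and Alox5ap at -0.27.

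Limma called 0 probe sets at day 14 with 4069 at an unadjusted p under 0.05. Without the 2 arrays that stand apart it called 0, with 1763 at an unadjusted p under 0.05, and without day14 replicate 1 it called 1. It called 0 against day 7, with 1676 at an unadjusted p under 0.05. Lists called were cytokine and acute phase genes (32 of 35 higher, median 0.14, adjusted p = 0.00381; adjusted p = 0.466 with an estimated correlation), with the chemokine genes Ccl7 at 0.72 (0.0396 over the list alone) and Ccl2 at 0.55; cell cycle genes (median 0.20, adjusted p = 0.00566; adjusted p = 0.421 with an estimated correlation), with Cdk1 at 0.39 and Aurkb at 0.33; and cholesterol genes (median -0.12, adjusted p = 0.0347; adjusted p = 0.466 with an estimated correlation). In the cholesterol list Fdft1 and Fdps were at -0.45 and -0.41 with day14 replicate 2 and at 0.01 and 0.01 without the 2 arrays, and the call was lost without day14 replicate 2 or control replicate 4, without the 2 arrays (adjusted p = 0.929), with the filter at the median probe set (0.202) and with the myelin covariate (0.0599). The mean of the cytokine list was 5.305, 5.680 and 5.361 in day14 replicates 1, 2 and 3, and without the 2 arrays 25 of 35 genes were higher, the median was 0.09 and the call was kept (adjusted p = 0.00624; 0.657 with an estimated correlation), with Ccl7 at 0.39 (0.0507 over the list alone) and Ccl2 at 0.26. The mean of the cell cycle list was 4.998, 5.401 and 5.022 in day14 replicates 1, 2 and 3, and without the 2 arrays that stand apart its median was 0.06 and the call was lost (adjusted p = 0.0669; 0.242 with a filter at the median probe set). The regeneration list was not called at day 14 (median 0.09, adjusted p = 0.169) and had adjusted p = 0.000796 without the 2 arrays (0.537 with an estimated correlation). Without day14 replicate 2 alone 9 lists were called.

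**Figure D3:**
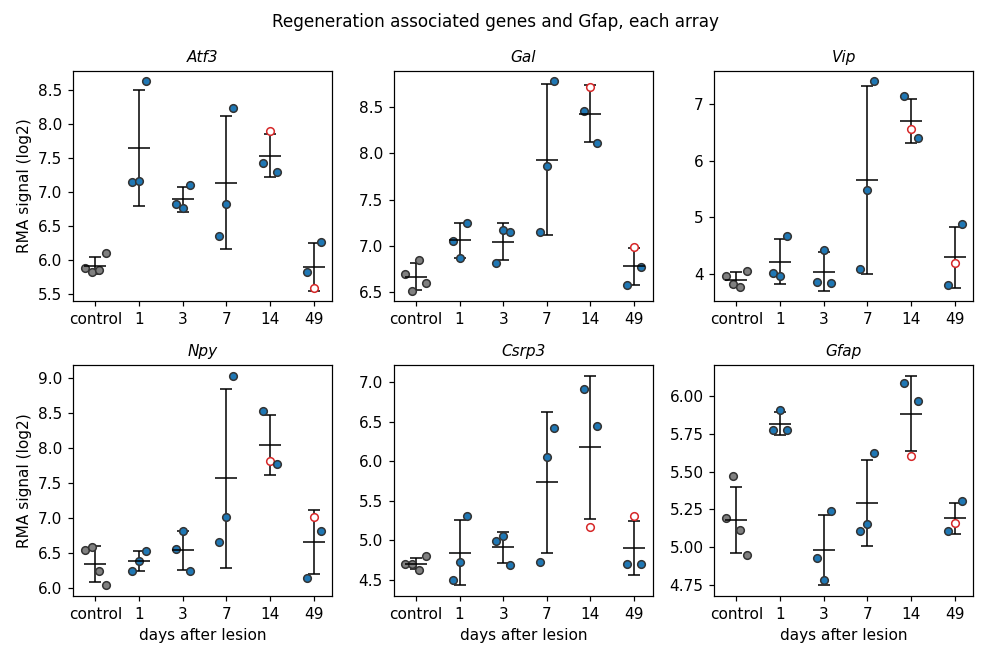
Each panel gives the RMA signal (log2) of 1 gene on each array by days after the lesion; bars are the group mean ± SD (n = 4 for control, 3 otherwise), grey points are control arrays, and open red points are day14 replicate 2 and day49 replicate 2. Vip has a mean of 3.90 in control and 6.70 at day 14, and Atf3 lies above all control arrays on each array from day 1 to day 14.

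The last comparisons asked what differed at day 49, against control and against day 14. Atf3, Gal and Gfap were near control: Atf3 was at 5.90 ± 0.35 (SD, n = 3) against 5.92, Gal at 6.78 ± 0.20 against 6.67 and Gfap at 5.19 ± 0.10 against 5.18. Limma called 0 probe sets against control, with 4783 at an unadjusted p under 0.05, and 0 against day 14, with 4423. Genes of smallest p, all with adjusted p = 0.306, were Chrm4 (0.48), Adcy10 (0.42), Slc26a5 (0.30), Tmem247 (0.51) and Sorbs3 (0.33) above control and Ppic (-0.42), Timp2 (-0.28), Cpne3 (-0.90), Serinc5 (-0.76) and Bcl10 (-0.31) below it. Adjusted over their own lists alone, the calcium-binding protein gene Calb1 (-0.94), the calcium channel subunit gene Cacnb4 (-0.66), Adamts5 (-0.59), Lamb1 (-0.39) and Crym (-0.27) were lower and the proteoglycan gene Ncan (0.33) higher; all but Crym were named after their values were seen. Without the 2 arrays that stand apart these were at -0.51, -0.44, -0.30, -0.25, -0.19 and 0.24, and over the list alone Cacnb4 passed (0.0365) and the other 5 did not (0.131 to 0.175).

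The day 49 result rested on single arrays. Without day49 replicate 1 limma called 2435 probe sets against control and 14 against day 14. The day 49 arrays left in that fit were day49 replicate 2, which stands apart, and day49 replicate 3. The latter had the highest beta-actin difference of the 17 other arrays (1.29). Array weights were 3.7 for day49 replicate 3, 0.385 for day49 replicate 1 and 0.067 for day49 replicate 2. With them limma called 6514 against control, in a fit whose day 49 mean rests mainly on day49 replicate 3. No list was called at day 49; 4 were without day49 replicate 2 and 1 was without control replicate 1, control replicate 3, day49 replicate 1 or day49 replicate 3.

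Over the time course as a whole, the moderated F test called 4 probe sets, those of Igfbp6 and Agt (both adjusted p = 0.0262), Spon2 (0.0336) and Crabp2 (0.0351), with 1368 at an unadjusted p under 0.05. Next by p came Lbp (0.0536), Lgi4 and Ifitm3 (both 0.0569), Pla1a (0.0728), Gal (0.12) and Rem2 (0.174). At days 7, 14 and 49 Agt was 0.16, -0.05 and 0.38 from control, Spon2 -0.06, 0.10 and 0.13, Crabp2 0.13, 0.18 and -0.14, Rem2 -0.04, -0.06 and 0.08, and Ifitm3 -0.13, 0.29 and -0.04. Days 14 and 49 include the 2 arrays that stand apart. Without them these days gave -0.08 and 0.22 for Agt, 0.05 and 0.035 for Spon2 and 0.16 and -0.06 for Crabp2. For Rem2 they gave -0.10 and 0.11, and for Ifitm3 0.27 and -0.08. The F count was 42 without the 2 arrays that stand apart and 0 with the replicate number as a block. It was 0 without control replicate 1, 2 or 4, any 1 of the 3 day 1 arrays, day3 replicate 1, day3 replicate 2, day7 replicate 2 or day14 replicate 1, 1 without day14 replicate 3, 7 without day3 replicate 3, 8 without day7 replicate 3 and 11 without day14 replicate 2.

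Genes named whatever they showed stayed within 0.5 of control on the log2 scale except Atf3, Gfap, Sprr1a at day 14 and Fos at day 49. Jun, a partner of Atf3, was 0.34, 0.28, 0.22, 0.10 and -0.17 from control at days 1, 3, 7, 14 and 49 (adjusted p between 0.458 and 1). Gap43 was between -0.06 and 0.13. The layer V transcription factor gene Bcl11b lay between -0.35 and 0.17, with the -0.35 of day 49 at 0.10 without the 2 arrays that stand apart, and the deep-layer gene Crym between -0.27 and -0.07. Fos was 0.18 above control at day 1 (adjusted p = 1) and 0.83 above it at day 49 (adjusted p = 0.308), and 0.36 without the 2 arrays.

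Cell type lists gave the change of marker RNA in the dissected tissue, which does not measure the share of each cell type. Over the 5 times, medians against control lay between -0.02 and 0.13 for layer V and corticospinal markers, -0.05 and 0.07 for layer VI and subplate, 0.01 and 0.15 for upper layers, 0.02 and 0.13 for interneurons and -0.02 and 0.07 for striatal neurons. They lay between -0.04 and 0.125 for microglia, -0.01 and 0.10 for astrocytes, -0.08 and 0.04 for oligodendrocytes, 0.01 and 0.11 for their precursors, -0.07 and 0.08 for endothelium, -0.09 and 0.15 for blood and -0.13 and 0.02 for meninges and choroid plexus. Several upper limits are day 14 medians that rest on day14 replicate 2: without the 2 arrays that stand apart the day 14 median went from 0.13 to 0.06 for layer V, 0.07 to -0.08 for layer VI, 0.15 to 0.04 for upper layers, 0.13 to 0.03 for interneurons, 0.07 to -0.01 for striatal neurons, 0.125 to 0.07 for microglia, 0.10 to 0.03 for astrocytes, 0.11 to 0.04 for oligodendrocyte precursors and 0.15 to 0.03 for blood. The day 49 median went from -0.05 to 0.05 for layer VI and from 0.02 to -0.06 for meninges and choroid plexus. In the fit of all 19 arrays, lists called at no time were those of layers V and VI, upper layers, striatum, excitatory synapses (medians of -0.0036 to 0.04), neurotrophic factors (0.00046 to 0.04), apoptosis (-0.03 to 0.01), heat shock (-0.09 to -0.0025), oxidative phosphorylation (-0.0012 to 0.06), astrocytes, oligodendrocytes, their precursors and blood. Of these, without the 2 arrays that stand apart apoptosis genes were called at day 7 (adjusted p = 0.0286; 0.383 with an estimated correlation) and oxidative phosphorylation genes at day 14 (0.0215; 0.777 with an estimated correlation), and with the beta-actin covariate excitatory synapse genes were called at day 7 (0.0251; 0.528 with an estimated correlation). With the replicate block the blood list was called at day 1 (0.0277; 0.357 with an estimated correlation) and day 3 (0.00169; 0.246). The median of all probe sets moved by at most 0.0674, at day 14.

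Against control, probe sets were called only at day 1, so no overlap of calls between times was possible. Log2 differences of different times share the 4 control arrays, which alone gives correlations of 0.426 to 0.431 across probe sets in simulation. Observed correlations were 0.187 to 0.558, and -0.0836 to 0.296 when each time was set against different control arrays. Across probe sets, which are not independent, the covariances of the 10 pairs of times were 0.00481 to 0.0299 against simulated values of 0.0141 to 0.0143, above the simulated value in 2 pairs. Without the 2 arrays that stand apart they were 0.00389 to 0.0122 against 0.00394 to 0.004, above it in 9 pairs. The simulation gave every array the shared spread of the fit, which the 2 arrays raise. For days 1 and 3, which hold neither array, the covariance was 0.00481 in both fits. The simulated value for these days was 0.0142 with all arrays and 0.00398 without the 2. The count of 2 pairs with all arrays therefore cannot tell whether the times share more than their controls.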

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

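Of the tests in this part, the one that leaves out each control array in turn and the counts of other splits without a block were planned; those on array quality, microglia, surface tissue and interneurons and the splits with the replicate block were chosen only after the results were seen.

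Between day 1 and day 3 the difference was tested in limma for every probe set, and it passed in 8: Igfbp6 (-1.17 and, in its other probe set, -1.14), Agt (-1.02), Ifitm3 (-1.07), Pla1a (-0.93), Spon2 (-0.85), Crabp2 (-0.73) and Lgi4 (-0.69). The 10 splits of these 6 arrays are too few for a share under 0.05; the highest count of any other split was 0. Day 1 against control uses the same day 1 arrays, so the 2 comparisons are not independent. For day 1 against control, without a block, the real split of the 7 arrays gave 11 probe sets, and the highest of the other 34 gave 0. The share of 1 of 35 is under 0.05 but the smallest that these splits can give, and they ignore the replicate number. With the replicate number as a block chance could not be excluded: the real split gave 3 probe sets, and 2 of 35 splits were as large, the highest other at 3. That other split is among the 8 that part the 3 pairs of like number as the real one does, too few for a share under 0.05; the 27 that part fewer gave 0. For the F test without a block the real grouping gave 4 probe sets. It is itself among the 100 splits counted, of which 2 were as large, and the other of these gave 6, above the real count. This share is under 0.05, but with the replicate block the count was 0, and splits of that fit were not counted. Chance is therefore not excluded for the F test.

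In the 4 control arrays, 1 array lay far from the other 3 in 5 of 134 sets of values (103 genes and 31 lists), where chance gives about 1 in 20. Control replicate 4 was at 4.92 for Agt against 4.81 to 4.83 (gap over range 0.862), at 10.61 for Insig1 against 10.40 to 10.43 (0.847) and at 5.33 for Fos against 5.73 to 5.77 (0.899). Control replicate 1 was at 9.38 for Ifitm3 against 9.48 to 9.50 (0.868) and at 3.42 for Wnt5a against 3.48 to 3.49 (0.911). The array control probe sets, which the comparisons did not use, gave values above all control arrays in day14 replicate 2 and day49 replicate 2. The GAPDH 3' minus 5' difference was 3.18 in day14 replicate 2 (control at most 0.11), the beta-actin difference 2.24 (control at most 1.09), and the spike mean 10.19 in day14 replicate 2 and 10.23 in day49 replicate 2 (control at most 9.518). Other arrays lay above all controls by less. Among them were day49 replicate 3 (beta-actin 1.29, GAPDH 0.196), day1 replicate 3 (beta-actin 1.26) and day3 replicate 2 (beta-actin 1.12, spike mean 9.721).

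The first pattern weighed is the large number of probe sets at an unadjusted p under 0.05 at day 14 (4069) and day 49 (4783), where 0 passed in limma after adjustment. Without day14 replicate 2 the day 14 count was 816, in a fit that still held day49 replicate 2, and without both arrays it was 1763, so damaged RNA on that array is a candidate explanation for a large part of it. Without both arrays that stand apart the day 49 count was 3738 against at most 1763 at days 3, 7 and 14, which argues against day49 replicate 2 as its whole source, although without that array alone, in a fit that still held day14 replicate 2, it was 1266. With the beta-actin difference as a covariate it was 1953 against at most 2046, so RNA integrity across the remaining arrays may account for the excess. Chance could not be excluded for either time, with 3 of 35 splits as large at each and highest others of 4587 and 6836; a lasting effect of the lesion at these times stays open.

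The second pattern is the lower interferon and antigen presentation list at days 1, 3 and 7 (means of -0.24, -0.23 and -0.22), which share the 4 control arrays and so are not 3 independent findings: the log2 differences of these days correlate by 0.381 to 0.558 across probe sets, and by -0.0836 to 0.031 against different controls. Fewer microglia would lower the microglia list alike, but its mean lay above that of the interferon list by at least 3.85 standard errors over members at each day. Those standard errors are over genes and not arrays. The day 1 arrays had microglia means of 6.451 to 6.644, above all 4 controls (6.378 to 6.443). But day3 replicates 1 and 2 (6.310 and 6.285) and day7 replicates 1 and 2 (6.348 and 6.367) lay below all 4 controls. Day7 replicate 3 (6.391) lay among the controls. Day3 replicate 3 (6.653) lay above them and had the highest interferon mean of its day. So fewer microglia stay open as a part at days 3 and 7. With each control array left out in turn the highest adjusted p was 3.12e-06 at the preset correlation, and the interferon mean lay between -0.281 and -0.1665. So no 1 control array carried the whole difference. This p-value and the standard errors take members as nearly independent, so they cannot exclude a part due to the controls. Control replicate 1 (6.995) lay below day1 replicate 3 (7.035) and day3 replicate 3 (7.033), and control replicate 4 was highest (7.261). The other arrays of these days lay below all 4 controls. With the beta-actin covariate the interferon mean was at least 1.12 times as far from 0, which argues against RNA integrity. Less surface tissue in the dissection would lower the meningeal and choroid plexus list alike: its mean lay above that of the interferon list by 2.43 standard errors at day 1. At days 3 and 7 the meningeal mean was lower too (-0.163 and -0.136) and lay above the interferon mean by only 1.13 and 1.63 standard errors. By that measure less surface tissue stays open at days 3 and 7. With the meningeal mean as a covariate, another kind of test, the interferon means of these 2 days kept at least 0.645 of their size. Their adjusted p was 9.58e-05 and 5.59e-05 at the preset correlation, which argues against surface tissue as the whole cause and leaves a part open. A lower interferon response after the lesion may be a hypothesis to follow up, but no call held with an estimated correlation (adjusted p = 0.078 at the lowest), and a sham operation, housing or infection were not tested.

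The third pattern is the higher Vip, Gal, Npy, Csrp3 and Atf3 at day 7 (mean 1.3) and day 14 (mean 1.87). More interneurons would raise their other markers, but 15 of these had a mean change of -0.00103 (SE over members 0.125) at day 14, against 2.25 for Vip and Npy. Without day14 replicate 2 the day 14 mean of the 5 genes was 1.944, and with the beta-actin covariate, without both arrays that stand apart, it was 1.907. This argues against the damaged array and RNA integrity as the source at day 14. None of these checks was run for day 7, where the interneuron list was itself called higher at the preset correlation. A response of axotomized neurons may be the explanation, as a hypothesis: the cell of origin was not tested, and the 5 genes were picked from these arrays. Each passed only when adjusted over the list alone at day 14.

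For the other results chance was judged by splits of the same arrays. It could not be excluded at day 3 (282 probe sets at an unadjusted p under 0.05, 14 of 35 splits as large, highest other 567) or day 7 (275, 10 of 35, highest other 901); 1 split for day 7 gave over 3 times the real count, which may point to a structure of the samples; none was identified. For lists at the preset correlation, 10 were called at day 3, with 1 of 35 splits as large and the highest other at 9. This is the smallest share that 35 splits can give, and no other time reached it. None of these lists was called with an estimated correlation (adjusted p = 0.078 at the lowest) or by fry, so chance is not excluded there. It could not be excluded at day 1 (13, 2 of 35, highest other 14), day 7 (7, 9 of 35, highest other 8), day 14 (3, 9 of 35, highest other 6) or day 49 (5 at an unadjusted p under 0.05, 20 of 35, highest other 10). For day 7 against day 3 (174, highest other 197), day 14 against day 7 (1676, highest other 1873) and day 49 against day 14 (4423, highest other 10333), all at an unadjusted p under 0.05, the 10 splits are too few for a share under 0.05.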

How the results depend on the processing

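The fits without day14 replicate 2 and day49 replicate 2, alone and with the beta-actin covariate, were chosen only after the results were seen; the other alternatives were planned. Of the 9 genes of day 1, Agt passed in 11 of 11 alternatives, Spon2 in 12 of 12, Crabp2 in 12 of 12, Igfbp6 in 11 of 12, Lbp in 10 of 11, Ifitm3 and Lgi4 in 10 of 12, Pla1a in 9 of 11 and Rem2 in 6 of 12. Agt, Lbp and Pla1a have 11 because their signal is too low for the filter at the median probe set, which leaves them untested. Of the 7 arrays compared, leaving out 1 in turn kept the call of Agt and Spon2 in 6, Crabp2 and Lbp in 5, Igfbp6 in 4, Pla1a, Lgi4 and Rem2 in 2 and Ifitm3 in 1. Of single-gene values under all alternatives, 3875 kept direction and side of the threshold, 126 kept direction and passed it, 79 kept direction and no longer passed, and 84 reversed, none of them called in either fit. For the lists called with all arrays at the preset correlation, 353 such values kept both, 109 were no longer called and 0 reversed; lists that gained a call are not in these counts. Signal over background was not analysed here, so small differences of weakly expressed genes are uncertain. Over all groups, replicate numbers were not taken to pair the samples. The correlation of deviations between arrays of like number had a median of 0.0706 over 45 pairs (-0.322 to 0.453) and was over 0.1 in 18. However, 13 of 18 arrays correlated best with an array of their own number. That is more than the share of such arrays among those they were compared with, though it was not tested and the labels name no pairing. A structure that follows the replicate number is therefore not excluded, and fits without the block ignore it. Leaving 1 array of 3 out keeps 2 in that group.

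The cause was not tested for the following changes, unless the alternative itself gives it. Array weights gave 6413 probe sets for the F test, 175 at day 1, 2 at day 3, 9 at day 14, 6514 at day 49, 491 for day 3 against day 1 and 2985 for day 49 against day 14. Fits of only the groups compared gave 19 at day 1, 3 at day 3, 1 at day 14 and 25 for day 3 against day 1. The replicate block gave 3 at day 1, where of the lists it changed only the cholesterol and blood calls (adjusted p of 0.0993 and 0.0277), and 0 for the F test. In the lists of other days the block ended the axon growth (0.0993), clock (0.0969), matrix and cholesterol (both 0.122) calls of day 3, the matrix call of day 7 (0.0814) and the cholesterol call of day 14 (0.109), and added the blood list at day 3 (0.00169) and the stress response list at day 7 (0.0412). Both added lists had adjusted p = 0.246 with an estimated correlation. Trend and robust settings gave 2 for the F test, quantile normalization again 1, and 1 probe set per gene 8, with fewer probe sets tested. The myelin covariate gave 80 probe sets at day 49 and 4 lists at day 3 and 8 at day 14. For lists, the estimated correlation gave 0 at day 1, 0 at day 3, 0 at day 7 and 0 at day 14, the filter 2 at day 49, and all probe sets of each gene 5 at day 14 and 2 at day 49. Without the 2 arrays that stand apart there were 68 probe sets at day 1, 63 for day 3 against day 1 and 42 for the F test, and 9 lists at day 14 and 3 at day 49. Adding the beta-actin covariate gave 81, 90 and 56 probe sets and 7 and 2 lists. With an estimated correlation neither fit called a list (adjusted p of 0.383 and 0.475 at the lowest).

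With each array left out in turn, counts of probe sets were 0 to 13 at day 1, 0 to 1 at day 14, 0 to 2435 at day 49 (2435 without day49 replicate 1), 0 to 8 for day 3 against day 1, 0 to 14 for day 49 against day 14 and 0 to 11 for the F test; in the other 4 comparisons they were 0. Counts of lists were 7 to 14 at day 1, 7 to 10 at day 3, 6 to 8 at day 7, 2 to 9 at day 14 and 0 to 4 at day 49.

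Reversed differences from control, on the log2 scale, were small and none was called in either fit. With each array centred on its median the value was at day 14 Igfbp6 0.0013. Quantile normalization again gave at day 14 Igfbp6 0.052, at day 49 Gap43 0.0011, Gfap -0.069, Crabp2 0.012, Lbp -0.10, Ifitm3 0.063. Array weights gave at day 3 Lgi4 0.0054, at day 14 Fdft1 0.0093, Fdps 0.023, Pla1a 0.059, at day 49 Atf3 0.32, Bcl11b 0.20, Crabp2 0.065, Ifitm3 0.12, Pla1a 0.065. The replicate block gave at day 3 Fos -0.015, at day 49 Atf3 0.040, Gfap -0.068, Igfbp6 -0.023, Lbp -0.028. The myelin covariate gave at day 7 Lbp 0.013, at day 14 Bcl11b -0.12, Igfbp6 0.0062, Lgi4 -0.023, Pla1a 0.062, at day 49 Pla1a 0.016. Leaving out the 2 arrays that stand apart gave at day 14 Fdft1 0.010, Fdps 0.012, Fos -0.030, Lgi4 -0.010, Pla1a 0.015, at day 49 Atf3 0.14, Bcl11b 0.10, Igfbp6 -0.021. Adding the beta-actin covariate to that gave at day 7 Lbp 0.060, at day 14 Fdft1 0.010, Fdps 0.013, Fos -0.014, Lgi4 -0.0035, Pla1a 0.022, at day 49 Sprr1a -0.036, Bcl11b 0.13, Pla1a 0.028, Gal -0.24. Leaving out each array in turn gave, from lowest to highest, at day 3 Sprr1a -0.074 to 0.0074, Fos -0.015 to 0.17, Agt -0.040 to 0.081, Spon2 -0.10 to 0.017, Crabp2 -0.0082 to 0.094, Pla1a -0.26 to 0.0064, at day 7 Gfap -0.051 to 0.21, Lbp -0.083 to 0.055, at day 14 Fdft1 -0.68 to 0.010, Fdps -0.63 to 0.012, Fos -0.030 to 0.83, Igfbp6 -0.13 to 0.11, Lgi4 -0.010 to 0.14, Pla1a -0.10 to 0.023, at day 49 Atf3 -0.21 to 0.14, Gfap -0.068 to 0.11, Bcl11b -0.64 to 0.10, Igfbp6 -0.074 to 0.14, Lbp -0.082 to 0.10, Ifitm3 -0.14 to 0.094, Pla1a -0.10 to 0.017.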

Other observations

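All tests in this part, on the regeneration list and the clock genes, were chosen only after the results were seen.

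Within day 7 the 3 arrays differed widely in genes of axon injury and neuropeptides, of which Csrp3 was named after its value was seen. Day7 replicate 3 had the highest and day7 replicate 1 the lowest value of Vip (7.41 and 4.08), Gal (8.78 and 7.15), Npy (9.03 and 6.65), Atf3 (8.24 and 6.36) and Csrp3 (6.42 and 4.72). Adamts4, a protease of the perineuronal net, was above control by 0.60 at day 1, 0.43 at day 3, 0.30 at day 7 and 0.47 at day 14, and passed when adjusted over the list alone at day 1 and, with all arrays, day 14 (0.033; 0.18 without the 2 arrays that stand apart).

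Atf3 lay above all 4 control arrays (5.84 to 6.11) on 12 of 12 arrays of days 1, 3, 7 and 14 (6.36 to 8.64). These days were put together after the values were seen, and the difference was not tested. The mean of the regeneration associated list at days 7 and 14 was 0.27 above control, with 5 of 6 arrays above all controls and a two-sided exact permutation p = 0.0238 over 210 splits, where the smallest possible is 0.00476; these days too were picked after their values were seen, so the p is no independent evidence.

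Clock genes at day 1 were examined for a different time of day of tissue collection. Among those named after their values were seen, Bmal1 (0.51) and Npas2 (0.34) were above control and Dbp (-0.95) and Nr1d2 (-0.59) below it, none past the threshold. The mean of 5 genes of the first kind was 0.27 above control and that of 9 of the second kind was at -0.30, a difference of 0.57 with 2 of 3 day 1 arrays above all controls. The two-sided exact permutation p = 0.114 over 35 splits, where the smallest possible is 0.0286, so the threshold was not passed. Within the 3 pairs of control and day 1 arrays of like number the difference was 0.685, 0.436 and 0.323, above 0 in 3 of 3, and each of the 4 named genes went 1 way in 3 of 3. The two-sided exact permutation of signs gives p = 0.25, the smallest that 3 pairs can give, so the time of collection stays open.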
